A study of Homo sapiens with 8 samples.

How the data were processed

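Poly(A) RNA of 8 HCT116 samples was sequenced, 4 labelled as PZH for 24 h and 4 as DMSO; what a replicate is, beyond its number, is not stated. Per the labels' protocols, total RNA was taken with Trizol, poly(A) RNA was enriched from it with magnetic beads, and libraries were made with the NEBNext Ultra RNA kit. The submitters' processing notes name FastQC 0.11.5, HISAT2 2.1.0, StringTie 1.3.3b and DESeq 1.28.0 without saying which step each served; the genome build, the annotation and the use of strand in counting are not given in the sources used here. The authors deposited 1 table of whole-number counts per gene symbol, with 1 column per library and no normalization, and 0 columns belonged to no sample. It holds 35394 genes, of which 4655 had no count in any library. A spreadsheet had turned 25 gene names into dates; these rows were kept under their dated names in library sizes and tests, are not named, and hold 0.178% to 0.220% of a library's counts.

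Total counts ran from 18144117 to 19917571 per library, and a floor of 3 counts corresponds to 0.151 to 0.165 CPM. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules. Replicates were compared before they were averaged: in every pair, counts differed by more than counting noise (chi-square per degree of freedom 2.39 to 2.81 among DMSO and 4.03 to 12.3 among PZH pairs, over genes with a summed count of at least 20), so none was treated as a duplicate. The biological coefficient of variation was 3.58% among DMSO and 8.02% among PZH libraries. The first principal component held 88.7% of the variance.

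Genes were kept by edgeR's filterByExpr with defaults (minimum count 10, minimum total count 15), which left 15006 genes. Libraries were scaled with TMM, and PZH was compared with DMSO by edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, default settings, group as the only term), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are PZH over DMSO. A standard error is the size of the log2 fold change divided by the square root of F. Levels per group are TMM-scaled CPM as mean ± SD, except that sums over markers of other cell types are CPM without scaling factors. For genes with 1 to 3 counts in a group, the ratio is given with a 95% exact binomial interval of the summed counts. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15.

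Before the data were examined, 42 gene lists were fixed, with 1169 entries, of which 1156 were in the table and 46 genes stood on more than 1 list. Those given here covered NRF2 targets, other antioxidant enzymes, ROS-producing oxidases, the ATF4 response, ER chaperones, heat shock, metallothioneins with a zinc transporter, DNA replication, mitosis, G1 regulators, DNA repair, genes for and against apoptosis, cholesterol synthesis and efflux, fatty acid synthesis and oxidation, Wnt targets, RAS-MAPK output, immediate early genes, NF-kB, interferon, class I antigen presentation, hypoxia and glycolysis, targets of the aryl hydrocarbon, bile acid and glucocorticoid receptors, autophagy, ferroptosis, MYC targets with ribosome assembly, ribosomal proteins, oxidative phosphorylation from both genomes, the proteasome, epithelial, mesenchymal and intestinal genes, and markers of fibroblasts, endothelial, immune and erythroid cells. Lists with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists; camera with an estimated correlation and fry were alternatives. Called list members are those past the adjusted threshold over all genes tested.

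The rule for named genes was also fixed before the data were examined: the 10 genes with the largest log2 fold change in each direction among called genes with a mean log2 CPM of at least 2, a symbol that is not a clone or LOC name, and groups that do not overlap; up to 4 members of each list with the smallest p among called members, or its 2 members with the smallest p where fewer than 2 were called; 21 index genes of redox, stress, growth and death; and markers of other cell types at 1 CPM or more. The rule allowed 180 genes, and the text names 147 of them; 26 from the lists were left out by hand after the values were seen, and 7 others and 1 list, left out whatever their values, are not reported here. Library measures (total counts, genes detected, shares of counts) were compared by exact two-sided permutation over 70 assignments, where the smallest p is 0.0286.

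Alternatives were RLE, upper quartile and no scaling factors, no filter, a filter of CPM of at least 1 in 4 libraries, DESeq2, limma-voom, robust empirical Bayes, the replicate number as a block, an adjusted p of 0.01 and leaving out each library. A fit with each library's GC trend removed (loess on transcript GC) and a fit without the 10 most abundant genes were chosen after seeing the data, as were leaving out each library for the library measures and fits with PZH replicates 3 and 4 only or 1 and 2 only. GENCODE 29 served for gene types, GC content and which genes overlap; 99.1% of tested symbols had a GC value. The test procedure was tested on simulated data for this comparison, with counts drawn for the real genes (14610 tested) and 200 genes changed: 56% of genes changed 1.25-fold were recovered, 74% at 1.5-fold, 86% at 2-fold and 96% at 4-fold, with 10 of 166 calls false, and 0 of 40 unchanged lists called by camera. Genes were drawn independently of each other, and the changed genes were few and even in direction. The simulation therefore does not show how the list test fares with correlated members, or scaling with a change as broad as the real one.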

Results

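HCT116 is a human colorectal cancer line. Cells were treated for 24 h with PZH (Pien Tze Huang), a traditional Chinese medicine formula, or received the solvent DMSO as the control, and their poly(A) RNA was sequenced. The study's title ties the medicine to reactive oxygen species (ROS) and to colorectal cancer growth, so the comparison asks which genes of oxidative stress, cell growth and other programmes differ between treated and control cells. There were 4 libraries per group. DMSO libraries held 19288836 to 19917571 counts and PZH libraries 18144117 to 18868057. Levels are in CPM, counts scaled to a common library size. No dose of PZH is given in the sources used here. The 10 most abundant genes took 6.31 ± 0.0893% of counts in DMSO and 11.0 ± 0.360% in PZH, and ribosomal protein genes 6.19 ± 0.181% and 7.76 ± 0.665% (mean ± SD, n = 4 per group; exact two-sided permutation p = 0.0286 for each, adjusted p = 0.04 over 7 measures). Total counts differed with the same p. Genes detected numbered 22750.5 ± 224 and 22317.75 ± 291 (exact permutation p = 0.114, adjusted p = 0.133), a difference that passed an unadjusted 0.05 on leaving out PZH replicate 3 (exact p = 0.0286).

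PZH-treated HCT116 cells showed a broad rearrangement of their transcriptome. As lists, targets of the antioxidant regulator NRF2, of the stress factor ATF4 and of the unfolded protein response were called higher. Of 35 tested NRF2 targets, 24 rose and 10 fell. Genes of DNA replication, mitosis, DNA repair and Wnt signalling were called lower as lists. Heme oxygenase HMOX1, which degrades heme, rose 22.6-fold from 21.4 ± 2.31 to 484 ± 10.7 CPM (mean ± SD, n = 4 per group). The proliferation marker MKI67 fell 10.1-fold from 929.8 ± 13.9 to 92.4 ± 10.2 CPM. Of 15006 genes tested, 5901 (39.3%) were higher and 6143 (40.9%) lower in PZH by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 2376 and 2835 differed at least 2-fold. A list whose members were called at shares near these differs little by count from all genes tested. The groups did not overlap for 11249 genes, where chance gives 2.86% of genes. With this many genes called, directions are relative to the scaling. Without scaling factors the median of all genes shifted by -0.26 on the log2 scale, and 4473 genes were higher and 7670 lower (1660 and 3779 at least 2-fold), which is 36.8% higher among calls against 49.0% in the main comparison.

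**Figure D1:**
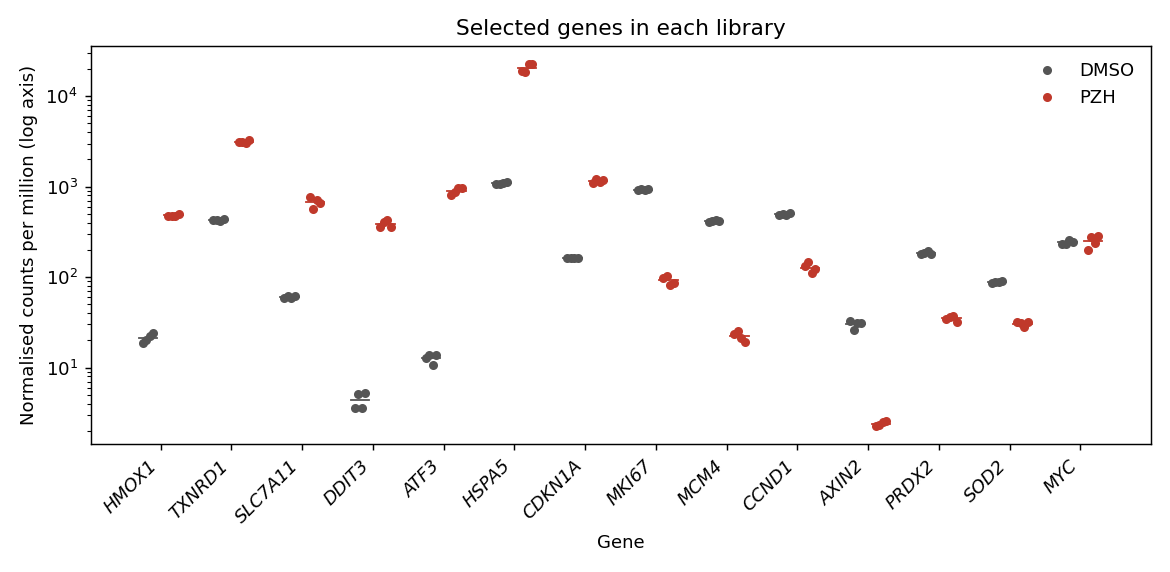
Normalised CPM on a log axis for 14 genes; each point is 1 library, grey for DMSO and red for PZH, and lines mark the group means. HMOX1, TXNRD1, SLC7A11, DDIT3, ATF3, HSPA5 and CDKN1A lie higher in PZH, MKI67, MCM4, CCND1, AXIN2, PRDX2 and SOD2 lie lower, and MYC overlaps between the groups.

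Among genes with a mean log2 CPM of at least 2, the steepest rises were those of the collagenase MMP1, the endothelial guidance receptor ROBO4, the peptide hormone gene SPX, BEST1, OLAH, LINC02273, UPP1, CXCL8, DDIT3 and IL31RA. The uridine phosphorylase UPP1 rose 95.03-fold from 15.01 ± 0.627 to 1428 ± 59.99 CPM (log2 fold change 6.57 ± 0.066, adjusted p = 4.15e-26). The neutrophil chemokine CXCL8 rose 94.1-fold and DDIT3, which encodes the stress transcription factor CHOP, rose 88.9-fold. MMP1 had 2 counts over the 4 DMSO libraries and 774 over the 4 PZH libraries, a ratio of 489 per unit depth with a 95% exact interval of 135 to 4042. ROBO4 had 3 and 1047 counts, a ratio of 441 with an interval of 150 to 2140. The steepest falls were those of MYB, CYP24A1, SMAD6, FNDC10, LFNG, SAMD1, RAB26, IGSF9, FAM111B and LRRC45. The proto-oncogene MYB went from 630 to 2 counts, a ratio of 249 with an interval of 68.8 to 2064. CYP24A1, the enzyme that inactivates vitamin D hormone, fell 101-fold from 172 ± 7.56 to 1.69 ± 0.289 CPM (log2 fold change -6.65 ± 0.084, adjusted p = 2.81e-24). SMAD6, an inhibitor of BMP signalling, fell 51.01-fold, and LFNG, a sugar transferase that modifies Notch, fell 41.3-fold. BEST1 overlaps FTH1, the ferritin heavy chain gene, on the opposite strand, and use of strand in counting is not given in the sources used here, so the value of BEST1 is uncertain.

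Genes of the antioxidant response divided into a group that rose and a group that fell. Of the NRF2 targets, 24 of 35 tested genes rose and 10 fell (camera adjusted p = 1.02e-14; adjusted p = 0.00341 with an estimated correlation). The redox regulator OSGIN1 rose 21.6-fold, thioredoxin reductase TXNRD1 rose 7.33-fold from 428 ± 5.67 to 3134 ± 86.9 CPM, GCLM of glutathione synthesis rose 6.17-fold and the quinone reductase NQO1 rose 1.97-fold. NFE2L2, which encodes NRF2, rose 2.55-fold, and its repressor KEAP1 had a log2 fold change of -0.12 ± 0.051 (adjusted p = 0.0327), a call that was lost with RLE factors (adjusted p = 0.0800), with DESeq2 (0.0889) and on leaving out DMSO replicate 1 (adjusted p = 0.0650), DMSO replicate 2 (0.0796), PZH replicate 2 (0.0771) or PZH replicate 4 (0.170). With the GC trend removed KEAP1 was called in the other direction (0.12, adjusted p = 0.0306). Antioxidant enzymes outside that list were called lower as a list, with 6 of 29 higher and 18 lower, or 3 and 23 without scaling factors (camera adjusted p = 0.0123; adjusted p = 0.443 with an estimated correlation). The peroxiredoxin PRDX2 fell 5.29-fold, mitochondrial superoxide dismutase SOD2 fell 2.88-fold, and the peroxidase GPX1, mitochondrial PRDX3 and GPX4 fell 2.54-fold, 1.89-fold and 1.65-fold. Catalase CAT did not pass the test, at 68.5 ± 1.59 CPM in DMSO and 71.8 ± 8.98 CPM in PZH, but was called lower without scaling factors (log2 fold change -0.19, adjusted p = 0.00707).

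Genes of ferroptosis and iron handling were called higher as a list, with 13 of 25 members higher and 8 lower (camera adjusted p = 2.16e-05; adjusted p = 0.0195 with an estimated correlation), or 12 and 10 without scaling factors. Cystine transporter SLC7A11 rose 11.2-fold, the glutathione-degrading enzyme CHAC1 rose 59.04-fold and FTH1 rose 10.5-fold from 548 ± 30.3 to 5735 ± 399.8 CPM. Of these, SLC7A11 and FTH1 are also on the NRF2 list, and SLC7A11 and CHAC1 on the ATF4 list. Part of the rise of this list is therefore shared with those responses. Genes of the zinc response, metallothioneins and a zinc transporter, were called higher as a list, with 4 of 5 members higher over all genes tested and 5 adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.0879 with an estimated correlation). MT1X rose 5.29-fold and MT2A rose 4.20-fold. Enzymes that produce ROS were not called as a list, with 3 of 15 higher and 6 lower, or 3 and 9 without scaling factors (camera adjusted p = 0.863). Here the oxidases ERO1B of the endoplasmic reticulum (ER) and SMOX of polyamine breakdown rose 5.26-fold and 2.34-fold, while monoamine oxidase MAOB and the NADPH oxidase subunit CYBA fell 7.50-fold and 2.27-fold. Over the 41 lists other than the zinc response, counts adjusted over the list alone were the same as those over all genes tested.

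ATF4 targets and ER chaperone genes were called higher as lists. Of the ATF4 targets, 34 of 37 rose and 1 fell (camera adjusted p = 5.74e-36; adjusted p = 0.00514 with an estimated correlation). ATF4 itself rose 3.76-fold, the transcription factor ATF3 rose 71.02-fold, the phosphatase subunit PPP1R15A rose 27.00-fold and the stress sensor SESN2 rose 28.3-fold (log2 fold change 4.82 ± 0.067, adjusted p = 7.30e-24). Genes of ER chaperones and the unfolded protein response were higher in 28 of 28 cases (camera adjusted p = 1.33e-27; adjusted p = 0.0452 with an estimated correlation). The chaperone HSPA5, also called BiP, rose 18.9-fold from 1096 ± 26.9 to 20698 ± 2187 CPM. DNAJB9, HERPUD1 and SELENOS, which serve ER folding and degradation, rose 14.8-fold, 14.8-fold and 5.27-fold. Heat shock genes were not called as a list, with 11 of 21 higher and 4 lower (camera adjusted p = 0.283; median log2 fold change 0.23, or -0.03 without scaling factors, with 10 higher and 8 lower). The heat shock genes DNAJB1, HSPB8, SERPINH1 and HSPA4L rose 3.99-fold, 3.91-fold, 2.25-fold and 2.20-fold. Of the tested heat shock genes, 20 of 21 stood higher in both PZH replicates 3 and 4 than in both replicates 1 and 2. Genes of other lists parted this way too: 13 of 28 ER genes and 13 of 13 mitochondrially encoded genes stood higher in replicates 3 and 4, and 27 of 40 mitotic genes lower. Over all tested genes 17.8% stood higher and 17.6% lower, 35.3% in all, where chance gives 33.3%. Replicates 1 and 3 parted from 2 and 4 in more genes, 37.9%, and 1 and 4 from 2 and 3 in fewer, 26.8%. Replicates 3 and 4 were the closest PZH pair (chi-square per degree of freedom 4.03, against 8.33 to 12.3). DNAJB1 stood at 757, 800, 1426 and 1505 CPM in PZH replicates 1 to 4, against 273 to 288 CPM in DMSO. Another 3 heat shock genes, outside the rule for named genes, lay below DMSO in replicates 1 and 2 and above it in replicates 3 and 4. In comparisons chosen after seeing the data, the heat shock list was called higher with PZH replicates 3 and 4 only (16 of 22 higher, 3 lower; camera adjusted p = 3.89e-08; adjusted p = 0.132 with an estimated correlation) and not called with replicates 1 and 2 only (10 of 21 higher, 8 lower; camera adjusted p = 0.0649).

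**Figure D2:**
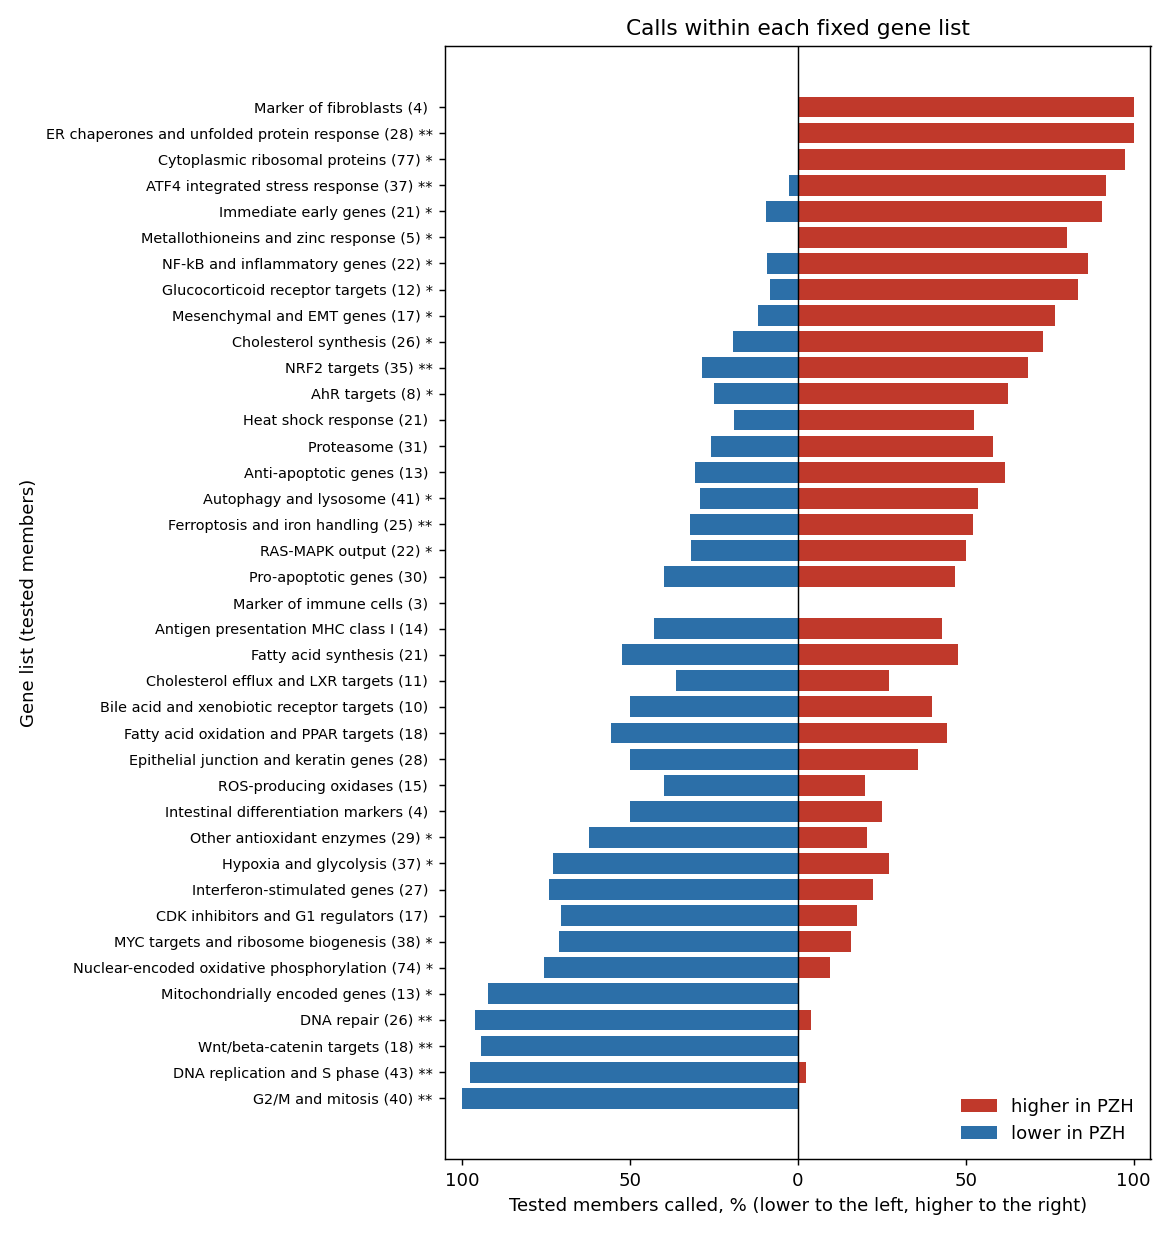
Share of the tested members of each of 39 gene lists that were called higher (red, to the right) or lower (blue, to the left) in PZH, in percent, with the number of tested members in brackets. One star marks a list called by camera and a double star one that also passed with an estimated correlation; ER chaperones lie wholly to the right and mitotic genes wholly to the left.

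Genes of DNA replication, mitosis and DNA repair fell together. Of the DNA replication genes, 42 of 43 fell and 1 rose (camera adjusted p = 1.46e-46; adjusted p = 0.00341 with an estimated correlation). The helicase subunits MCM2 and MCM4 fell 12.02-fold and 18.7-fold (log2 fold change -4.23 ± 0.064, adjusted p = 1.87e-23), thymidine kinase TK1 fell 6.49-fold and UHRF1, a partner of DNA methylation, fell 9.73-fold. All 40 genes of G2 and mitosis fell (camera adjusted p = 4.76e-40; adjusted p = 0.0452 with an estimated correlation). The mitotic kinesin KIF20A, the cytokinesis gene ANLN and cyclin CCNA2 fell 11.8-fold, 5.80-fold and 6.68-fold. DNA repair genes fell in 25 of 26 cases and 1 rose (camera adjusted p = 5.06e-10; adjusted p = 0.0452 with an estimated correlation), with FANCA, CLSPN and BRIP1 lower by 5.85-fold, 5.84-fold and 7.78-fold. Among CDK inhibitors and G1 regulators, which were not called as a list (camera adjusted p = 0.0903), 3 of 17 rose and 12 fell, or 2 and 13 without scaling factors. Cyclin CCND1 fell 3.88-fold, CDK2 fell 2.62-fold and the inhibitor CDKN2C fell 12.9-fold, whereas the inhibitor CDKN1A (p21) rose 7.09-fold from 164 ± 1.58 to 1159 ± 54.7 CPM.

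Pro-apoptotic genes were not called as a list, with 14 of 30 higher and 12 lower (camera adjusted p = 0.283), or 10 and 14 without scaling factors, where the median turned from 0.10 to -0.16. TNFRSF10B, a receptor for the death ligand TRAIL, rose 9.57-fold, PMAIP1 (NOXA) and the death receptor TNFRSF1A rose 3.13-fold and 2.29-fold, and the effector BAX and the caspase CASP2 fell 1.61-fold and 3.19-fold. Anti-apoptotic genes were not called either, with 8 of 13 higher and 4 lower (camera adjusted p = 0.134). The caspase inhibitors BIRC2 and XIAP and the survival factor MCL1 rose 2.89-fold, 2.64-fold and 2.56-fold, and BIRC5 (survivin) and BCL2 fell 10.2-fold and 2.63-fold.

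Wnt target genes fell, in a line whose beta-catenin is mutated. Of 18 tested, 17 fell and MYC did not pass (camera adjusted p = 1.33e-10; adjusted p = 0.00971 with an estimated correlation); without scaling factors 18 fell. The feedback inhibitors AXIN2 and DKK1 fell 12.5-fold and 24.8-fold, and the transcription factors SOX4 and SOX9 fell 16.9-fold and 4.24-fold. The oncogene MYC stood at 242 ± 10.8 CPM in DMSO and 250.0 ± 40.1 CPM in PZH, but it was called higher without PZH replicate 1 (log2 fold change 0.16, adjusted p = 0.0125) and lower without scaling factors (-0.22, adjusted p = 0.00638). Genes driven by RAS and ERK were called higher, with 11 of 22 higher and 7 lower (camera adjusted p = 2.61e-04; adjusted p = 0.135 with an estimated correlation), or 11 and 9 without scaling factors, where the median went from 0.29 to 0.0341. The phosphatase DUSP5, the growth factor AREG and the transcription factors FOSL1 and EGR1 rose 18.1-fold, 9.07-fold, 9.24-fold and 20.2-fold.

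Immediate early genes were higher in 19 of 21 cases and lower in 2 (camera adjusted p = 4.79e-13; adjusted p = 0.0879 with an estimated correlation). JUN rose 37.2-fold and the phosphatase DUSP1 rose 25.5-fold. NF-kB and inflammatory genes were higher in 19 of 22 cases and lower in 2 (camera adjusted p = 2.52e-06; adjusted p = 0.0726 with an estimated correlation), among them the iron-binding lipocalin LCN2 (32.03-fold higher) and the NF-kB subunit RELB (8.30-fold higher). Interferon-stimulated genes were not called as a list, with 6 of 27 higher and 20 lower (camera adjusted p = 0.404). ISG20 and IRF7 rose 21.2-fold and 9.84-fold, and the antiviral genes OAS3 and IFIT1 fell 11.5-fold and 12.8-fold. Genes of class I antigen presentation went both ways, 6 higher and 6 lower of 14, or 5 and 8 without scaling factors (camera adjusted p = 0.877), with HLA-B 2.61-fold higher and TAPBP 1.76-fold lower.

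Hypoxia and glycolysis genes were lower in 27 of 37 cases and higher in 10 (camera adjusted p = 0.00300; adjusted p = 0.465 with an estimated correlation). Lactate dehydrogenase LDHA fell 5.56-fold from 1570.5 ± 58.5 to 283 ± 16.2 CPM, the glycolytic enzymes GPI and PGAM1 fell 5.64-fold and 4.16-fold, and the angiogenic factor VEGFA rose 5.57-fold. Nuclear genes of oxidative phosphorylation were lower in 56 of 74 cases and higher in 7, or 67 and 4 without scaling factors (camera adjusted p = 2.15e-04; adjusted p = 0.452 with an estimated correlation), with NDUFB10 of complex I and ATP5MC1 of ATP synthase lower by 4.10-fold and 3.002-fold. Protein-coding genes of the mitochondrial genome were lower in 12 of 13 cases, and the other was not called (camera adjusted p = 2.15e-04; adjusted p = 0.443 with an estimated correlation); without scaling factors 13 were lower. MT-ND6 and MT-ND3 fell 4.60-fold and 4.25-fold. Mitochondrial rRNA went the opposite way, from 1.02 ± 0.0407% to 2.96 ± 0.0738% of counts, while mitochondrial mRNA went from 3.63 ± 0.163% to 1.64 ± 0.145% (exact two-sided permutation p = 0.0286 for each, the smallest that 70 assignments allow; Benjamini-Hochberg adjusted p = 0.04 over 7 measures). The whole mitochondrial share was 4.64 ± 0.203% in DMSO and 4.60 ± 0.129% in PZH (exact permutation p = 0.8286, also after adjustment).

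**Figure D3:**
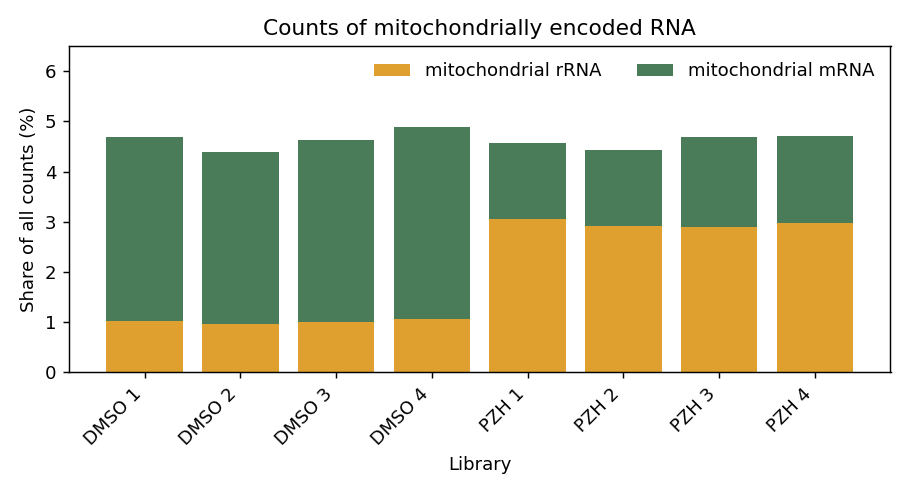
Share of all counts, in percent, from mitochondrially encoded rRNA (yellow) and mRNA (green), stacked, 1 bar per library. The rRNA part averages 1.02% in the 4 DMSO libraries and 2.96% in the 4 PZH libraries, while the sum stays between 4.39% and 4.88%.

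Cholesterol synthesis genes were higher in 19 of 26 cases and lower in 5 (camera adjusted p = 2.45e-04; adjusted p = 0.443 with an estimated correlation). The sterol oxidase MSMO1 and the cholesterol carrier STARD4 rose 7.55-fold and 3.60-fold, while LSS, the lanosterol synthase, fell 4.86-fold. Other lipid lists were not called. Fatty acid synthesis genes were 10 higher and 11 lower of 21 (camera adjusted p = 0.511), with malic enzyme ME1 and the phosphatidate phosphatase LPIN1 3.77-fold and 3.40-fold higher. Fatty acid oxidation genes were 8 higher and 10 lower of 18 (camera adjusted p = 0.918), with the lipid droplet protein PLIN2 3.50-fold higher and the carnitine transferase CPT1A 2.34-fold lower. LXR targets and cholesterol efflux genes were 3 higher and 4 lower of 11 (camera adjusted p = 0.932), with the transfer protein PLTP 5.86-fold higher and SREBF1 1.91-fold lower. For fatty acid synthesis and for cholesterol efflux the median was below 0 (-0.18 and -0.11) and the mean above 0 (0.12 and 0.13).

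Autophagy and lysosome genes were called higher, with 22 of 41 higher and 12 lower (camera adjusted p = 0.00300; adjusted p = 0.0726 with an estimated correlation; median 0.21, or -0.05 without scaling factors, with 19 higher and 16 lower). The autophagosome protein MAP1LC3B rose 23.1-fold from 119 ± 3.93 to 2732 ± 209.6 CPM, and the cargo receptors SQSTM1 and OPTN rose 6.07-fold and 6.005-fold. Proteasome subunits were not called as a list, with 18 of 31 higher and 8 lower (camera adjusted p = 0.511), or 11 and 15 without scaling factors, where the median turned from 0.17 to -0.09. PSMC4 rose 1.89-fold and PSMD1 fell 1.85-fold. MYC targets and ribosome assembly genes, fixed as 1 list, were lower in 27 of 38 cases and higher in 6, or 32 and 4 without scaling factors (camera adjusted p = 0.00422; adjusted p = 0.443 with an estimated correlation), with POLR1A and NHP2 lower by 2.44-fold and 3.07-fold and RRP12 higher by 2.92-fold. Cytosolic ribosomal proteins were higher in 75 of 77 cases and not called in the others; without scaling factors 65 were higher and 3 lower (camera adjusted p = 1.20e-05; adjusted p = 0.622 with an estimated correlation). RPL10 and RPS13 rose 2.15-fold and 1.93-fold, but many ribosomal protein genes have near-identical pseudogenes, so their single values are uncertain.

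Targets of ligand-activated receptors were also examined. Glucocorticoid receptor targets were higher in 10 of 12 cases and lower in 1 (camera adjusted p = 1.20e-05; adjusted p = 0.205 with an estimated correlation), with GADD45B and TSC22D3 (GILZ) 14.6-fold and 6.63-fold higher. Targets of the aryl hydrocarbon receptor were higher in 5 of 8 cases and lower in 2, or 4 and 3 without scaling factors (camera adjusted p = 0.00949; adjusted p = 0.326 with an estimated correlation), with TIPARP 5.02-fold higher. Among the members that rose, NQO1 is also on the NRF2 list, another is on the ATF4 list, and NFE2L2 encodes NRF2. Part of this rise is therefore shared with those responses. Bile acid and xenobiotic receptor targets were not called, 4 higher and 5 lower of 10 (camera adjusted p = 0.877). FGF19 and the drug efflux pump ABCB1 rose 4.82-fold and 6.85-fold, while CYP24A1, named above among the steepest falls, is also on this list.

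Genes of epithelial junctions and keratins were not called as a list, with 10 of 28 higher and 14 lower (camera adjusted p = 0.646), or 7 and 19 without scaling factors, where the median went from -0.12 to -0.38. The junction genes CDH1, CLDN7 and OCLN rose 3.12-fold, 3.97-fold and 4.47-fold. Mesenchymal and EMT genes were called higher, with 13 of 17 higher and 2 lower (camera adjusted p = 1.69e-05; adjusted p = 0.193 with an estimated correlation). The urokinase receptor PLAUR rose 5.95-fold. Of 4 tested intestinal differentiation markers, KLF4 rose 3.25-fold and CDX2 and CA2 fell 1.45-fold and 1.70-fold (camera adjusted p = 0.877 for the list). For antigen presentation and epithelial genes the median and mean lay below 0 although camera's direction was up; for intestinal markers the median lay below 0 and the mean above.

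Markers of cell types other than HCT116 were low. Their summed levels and the p-values of these sums are for CPM without scaling factors, unlike the values of single genes. The summed level of 11 fibroblast markers was 16.5 ± 1.15 CPM in DMSO and 25.3 ± 2.51 CPM in PZH (exact permutation p = 0.0286), and 4 of 4 tested members rose (camera adjusted p = 0.511, not called as a list), or 3 of 4 without scaling factors. COL1A1 and COL6A3 rose 1.77-fold and 4.02-fold. The 10 endothelial markers summed to 10.7 ± 0.643 and 5.87 ± 0.417 CPM (exact permutation p = 0.0286), with 1 of 2 tested members lower, ESAM, by 1.81-fold; the other, ENG, was not called (log2 fold change 0.21 ± 0.33, adjusted p = 0.572). The 18 immune markers summed to 5.06 ± 3.19 and 6.34 ± 2.47 CPM (exact permutation p = 0.486), with 3 members tested, 0 called by edgeR (1 at an unadjusted p under 0.05; 0 called by DESeq2 and 1 by limma-voom) and a camera adjusted p of 0.918. The leukocyte gene PTPRC (log2 fold change 1.70 ± 0.79, adjusted p = 0.0544) had 20 counts over the DMSO libraries, all in replicate 1, and 52 over the PZH libraries. In CPM it stood at 0.913 in DMSO replicate 1 and 0.0566 in PZH replicate 1, against 1.004 to 1.03 in the other PZH libraries. It was called higher with no filter (adjusted p = 0.00276), with limma-voom (0.00478), with the replicate number as a block (0.0397), and on leaving out DMSO replicate 1 (adjusted p = 8.28e-05) or PZH replicate 1 (0.0117). CD74 of class II antigen presentation had a log2 fold change of 0.22 ± 0.58 (adjusted p = 0.738) and was called higher without DMSO replicate 1 (adjusted p = 0.0277). It stood at 1.83 CPM in DMSO replicate 1, against 0.191 to 0.426 CPM in the other DMSO libraries. In PZH it stood at 0.113 CPM in replicate 1 and 0.725 to 1.21 CPM in the others. The levels of PTPRC and CD74 thus parted the libraries across the treatments, and neither gene was higher in every PZH library. HLA-DRA was at 1.95 ± 0.122 and 1.96 ± 0.332 CPM (adjusted p = 0.9988). The 7 erythroid markers summed to 8.27 ± 0.843 and 6.72 ± 0.999 CPM (exact permutation p = 0.0857), with 1 member tested, the fetal globin HBG2, and not called (log2 fold change 0.0200 ± 0.14, adjusted p = 0.898). Without scaling factors, as in the sum, the log2 fold change of HBG2 was -0.24.

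Camera called 15 of 40 lists higher and 9 lower, and 5 and 4 of these passed with an estimated correlation. Nothing in the sources used here says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Of 147 named genes, 41 overlap another tested gene in GENCODE 29, which may not be the annotation the authors counted on, mostly on the opposite strand, so part of their counts may belong to a neighbour; ACTA2, BEST1, DDIT3, HBG2, HLA-B, IFIT1, LRRC45, PLTP and SOD2 each have a neighbour with more counts. FTH1, HLA-B, MT1X and MT2A belong to families of near-identical copies, and their values are uncertain where counting could split reads between copies.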

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

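Tests of the patterns weighed here were chosen only after the results were seen. In 20 of 308 groups of 4 values, 1 library lay far from the rest of its group by Dixon's criterion; chance gives about 15 of 308. All of these are CPM of single genes and no library measure was among them.

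Among the DMSO libraries, MMP1 stood at 0.0931 CPM in DMSO replicate 3, against 0 CPM in the others, and OLAH at 0.0478 CPM in DMSO replicate 4, against 0.0913 to 0.0947 CPM. IL31RA stood at 0.615 CPM in DMSO replicate 2, against 0.183 to 0.233 CPM in the others, and RAB26 at 13.3 CPM in DMSO replicate 1, against 16.7 to 16.9 CPM. NQO1 stood at 415 CPM in DMSO replicate 2, against 399 to 401 CPM in the others, and UHRF1 at 125 CPM in DMSO replicate 2, against 133 to 135 CPM. XIAP stood at 60.8 CPM in DMSO replicate 1, against 56.5 to 57.2 CPM in the others, and IFIT1 at 11.9 CPM in DMSO replicate 3, against 9.61 to 9.86 CPM. PGAM1 stood at 559 CPM in DMSO replicate 4, against 538 to 541 CPM in the others, and TIPARP at 41.5 CPM in DMSO replicate 4, against 45.8 to 46.5 CPM. PTPRC stood at 0.913 CPM in DMSO replicate 1, against 0 CPM in the others, and CD74 at 1.83 CPM in DMSO replicate 1, against 0.191 to 0.426 CPM.

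Among the PZH libraries, MYB stood at 0.113 CPM in PZH replicate 1, against 0 CPM in the others, and HMOX1 at 499.8 CPM in PZH replicate 4, against 478 to 479.6 CPM. CHAC1 stood at 190.2 CPM in PZH replicate 1, against 214 to 215 CPM in the others, and BCL2 at 1.59 CPM in PZH replicate 2, against 2.36 to 2.38 CPM. BIRC2 stood at 163 CPM in PZH replicate 2, against 181 to 183 CPM in the others, and XIAP at 164 CPM in PZH replicate 1, against 148 to 149.7 CPM. GADD45B stood at 136 CPM in PZH replicate 1, against 173 to 178 CPM in the others, and PTPRC at 0.0566 CPM in PZH replicate 1, against 1.004 to 1.03 CPM.

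For the breadth of the difference between PZH and DMSO, the 35 splits of the 8 libraries into groups of 4 were compared. The real split gave 5901 genes higher and 6143 lower, with 2376 and 2835 changed at least 2-fold. The highest of the other splits was 0 each time by edgeR (at most 383 genes at an unadjusted p under 0.05, 0 called by limma-voom). The real split thus led at 1 of 35, the smallest share possible. Every other split mixes the treatments, so the difference between them enters the spread. A count of 0 there therefore does not measure what chance alone gives. Counted in either direction, since a split and its mirror are 1, 15 or more lists came from 1 of 35 splits, again the smallest share possible. The highest other split gave 12. Counted the same way, 17 of 35 splits gave the 9 lists called lower or more, and the highest other gave 12. This count cannot decide on chance. The other 16 put 3 libraries of one treatment with 1 of the other, so part of the treatment difference remains in them. Also, the larger of the higher and lower counts of each was set against the 9 of the real split, whose larger count was 15. Among the 18 splits with 2 of each treatment the highest was 4. A GC trend as the whole cause is argued against, since 94.5% of calls stayed in their direction with each library's trend removed, and so is scaling as the cause of every call, since 1 factor per library moves all genes alike yet 4473 genes were called higher and 6007 lower under each of 4 scalings; the balance between higher and lower follows the scaling, and an effect of the treatment stays open, as does any change in total RNA per cell, which relative counts cannot show.

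Mitochondrial rRNA was higher and mitochondrial mRNA lower in PZH. Scaling as the cause is argued against, because 2 of 2 mitochondrial rRNAs still passed as higher (log2 fold change 1.83 for MT-RNR1 and 1.503 for MT-RNR2) and 13 mRNAs as lower without scaling factors. More or fewer mitochondria as the whole cause is argued against by the log2 ratio of rRNA to mRNA counts, which was -1.84 ± 0.0178 in DMSO and 0.856 ± 0.147 in PZH (SD, n = 4; shift 2.69; exact permutation p = 0.0286). A greater carry-over of RNA without a long poly(A) tail adds RNA. The fall of the mRNAs, 12 of 13 with scaling factors and 13 without, argues against it as the cause of that part. For the rise of the rRNAs, such a carry-over and a biological change in mitochondrial RNA cannot be told apart here, because 0 untailed nuclear RNAs reached a mean log2 CPM of 2. The 12 tested had a median log2 fold change of 0.65, with 5 higher and 2 lower by edgeR.

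BEST1 rose among the most although it overlaps FTH1, which rose too. A constant share of FTH1 reads counted for BEST1 is argued against: the log2 ratio of BEST1 to FTH1 counts was -13.0 ± 0.610 in DMSO and -8.74 ± 0.282 in PZH, a shift of 4.27 with no overlap (exact permutation p = 0.0286). BEST1 had 1, 2, 1 and 2 counts in the DMSO libraries. A share of such reads that itself differs between the groups, and transcription of BEST1, stay open, since strand is not known here.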

How the results depend on the processing

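Other settings left most results in place; the fit with the GC trend removed and the fit without the 10 most abundant genes were chosen after seeing the data, as was leaving out libraries for the library measures. Of 147 named genes, 138 kept their direction and their side of the threshold in all settings that gave a value. The 9 exceptions were KEAP1, CAT, MYC, ACTA2, ENG, HLA-DRA, HBG2, PTPRC and CD74; the causes were not tested. KEAP1 turned to 0.12 with the GC trend removed, a call as higher. CAT turned to -0.00812 with upper quartile scaling, -0.19 without scaling factors, a call as lower, and, on leaving out 1 library, ranged from -0.00253 (without PZH replicate 2) to 0.13 (without PZH replicate 3). MYC turned to -0.0274 with upper quartile scaling, -0.22 without scaling factors, also a call as lower, -0.00080 without PZH replicate 2 and -0.0181 without PZH replicate 4, and reached 0.16 without PZH replicate 1. ACTA2 lost its call without scaling factors. ENG turned to -0.0444 without scaling factors and ranged from -0.00566 (without PZH replicate 1) to 0.42 (without DMSO replicate 3). HLA-DRA turned to -0.0734 with upper quartile scaling, -0.26 without scaling factors, -0.0136 with no filter, -0.0113 with limma-voom, -0.00523 with the replicate block and -0.0284 with the GC trend removed, and ranged from -0.0639 (without PZH replicate 4) to 0.11 (without PZH replicate 1). HBG2 turned to -0.0536 with upper quartile scaling and -0.24 without scaling factors, and ranged from -0.0493 (without PZH replicate 3) to 0.14 (without PZH replicate 1). CD74 turned to -0.0470 without scaling factors and ranged from -0.0866 (without DMSO replicate 4) to 1.45 (without DMSO replicate 1). PTPRC kept its direction but was called in 5 alternatives: 1.70 with no filter, 3.21 with limma-voom, 1.93 with the replicate block, 6.87 without DMSO replicate 1, the highest of the range, and 2.12 without PZH replicate 1; the lowest was 1.29 (without DMSO replicate 3). Leaving out 1 library gave 5835 to 5991 genes higher, 6026 to 6217 lower, 2424 to 2497 at least 2-fold higher, 2886 to 3033 at least 2-fold lower, and 15 lists higher and 9 lower throughout. The filter was applied anew in each of these fits, which tested 15256 to 15371 genes, against 15006 in the main fit. Both main 2-fold counts, 2376 and 2835, lie below the ranges given, so these ranges do not reflect single libraries alone. Other alternatives gave 4473 (no scaling factors) to 6713 (no filter) genes higher and 5661 (adjusted p under 0.01) to 7670 (no scaling factors) lower, and 1660 (no scaling factors) to 3316 (no filter) at least 2-fold higher and 2555 (CPM of at least 1 in 4 libraries) to 3779 (no scaling factors) at least 2-fold lower. PZH replicates 3 and 4 only, and replicates 1 and 2 only, also chosen after seeing the data and run for the counts and the heat shock list, gave 6036 and 5792 genes higher, 6185 and 5962 lower, 2638 and 2434 at least 2-fold higher, 3101 and 2977 at least 2-fold lower, 17 and 15 lists higher, and 9 lower in both. The replicate number as a block gave 5889 higher and 6125 lower; deviations of same-numbered libraries correlated at 0.000736, 0.0113, 0.00231 and 0.00804, and 1 of 4 numbers had its own partner as the best match, so the numbers were not taken to pair the libraries. The number of lists called higher fell from 15 to 5 and of those lower from 9 to 4 with an estimated correlation. Correlated members alone do not account for this fall. The autophagy list had an estimated correlation of 0.0104, near the preset 0.01. Its unadjusted camera p still went from 0.00156 to 0.0200, and the call was lost. NRF2 targets had 0.00763, below the preset, and their unadjusted camera p went from 1.28e-15 to 1.71e-04. The number higher went to 23 with fry, which does not compare a list with other genes. Among 561 alternatives for single lists, 15 lost the call, all 15 with an estimated correlation, 13 gained it, 12 with fry and heat shock with PZH replicates 3 and 4 only, and 0 reversed by limma's tests. The difference in the whole mitochondrial share (PZH minus DMSO) ranged from -0.127 without DMSO replicate 2 to 0.0372 without DMSO replicate 4, and was 0.0159 without PZH replicate 2. Depth limits genes near 3 counts per library.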

Other observations

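Gene families in this part, and all tests on them, were chosen only after the data were seen. Genes of ER and Golgi transport vesicles (COPI and COPII coats, and SEC22B) were higher in 19 of 20 cases and lower in 1 (camera adjusted p = 1.60e-10 over 7 families, and adjusted p = 0.130 with an estimated correlation). Of these, SEC22B is not a coat protein, and SEC24D is also on the fixed list of ER chaperones. The log2 fold change was 2.03 ± 0.056 for SEC24D, 1.74 for SEC23B and 1.57 for COPA. Noncoding host genes of small nucleolar RNAs (SNHG genes and GAS5) were higher in 15 of 20 cases and lower in 2 (camera adjusted p = 0.00706 over 7 families; adjusted p = 0.177 with an estimated correlation), with GAS5 at 2.53 ± 0.076 and SNHG8 at 2.003. Splicing factors of the SR and hnRNP families, without 13 pseudogenes, went down in 25 of 32 cases and up in 5, or 27 and 1 without scaling factors (camera adjusted p = 3.16e-06 over 7 families; adjusted p = 0.130 with an estimated correlation), with HNRNPM at -2.16 ± 0.059 and SRSF7 at -1.66. Mitochondrial ribosomal proteins, without 4 pseudogenes, were lower in 50 of 77 cases and higher in 14, or 62 and 5 without scaling factors (camera adjusted p = 0.0189 over 7 families; adjusted p = 0.445 with an estimated correlation), where cytosolic ones were higher in 75 of 77. Tubulins were not called as a family, with 4 of 12 higher and 6 lower (camera adjusted p = 0.121 over 7 families; adjusted p = 0.445 with an estimated correlation).

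Synthetases that load tRNAs were compared by compartment. Cytosolic synthetases were higher in 13 of 20 cases and lower in 5, or 10 and 7 without scaling factors, where the median went from 0.33 to 0.0718 (camera adjusted p = 2.14e-04 over 7 families; adjusted p = 0.159 with an estimated correlation), with AARS at 2.13 and SARS at 2.11 on the log2 scale. Mitochondrial synthetases were lower in 13 of 17 cases and higher in 4, or 13 and 2 without scaling factors (camera adjusted p = 0.0466 over 7 families; adjusted p = 0.159 with an estimated correlation), with CARS2 at -1.36. The mean log2 fold change was 0.66 for the cytosolic and -0.50 for the mitochondrial family, a difference of 1.16 (permutation p = 0.00014 over 100000 resamples of genes, which are not independent replicates). Since both families missed the threshold with an estimated correlation, this does not establish that they part. One hypothesis is that ATF4 drives the difference. Of the 20 cytosolic genes, 7 stand on the ATF4 list, and without them the difference was 0.71 (permutation p = 0.00552), but control of the other 13 by ATF4 was not measured, so the hypothesis stays open. GARS and KARS serve both compartments.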
